A study of Mus musculus with 6 samples.

How the data were processed

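RNA of 6 samples labelled as mouse aorta, 3 of Trail knockout and 3 of wild type, was measured on one-colour Affymetrix arrays. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was made from 6 ug. Groups and replicate numbers were taken from the sample titles. The deposited table holds 1 column of log2 values per sample for 35399 probe sets, and no column was left without a sample. The log base is not stated and was read from the range of the values, 1.55 to 13.96. The submitters' processing notes name MAS5, with no version or role, and the background correction, summary method and scaling between arrays are not given in the sources used here. Linear MAS5 signals would exceed this range, so the values were used as deposited, with no pseudocount and no further scaling. How the values were summarised could change small differences of dim genes, and no detection calls were used here.

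Probe sets were named through the platform annotation, which lists 23410 of them. Of these, 21789 have 1 gene symbol and 1621 have several, and none was named from several. The other 11989 are unnamed here and were left out of the main test, since control probe sets could not be told from the rest. The plan had foreseen control probe sets with names of their own. A run over all probe sets was added after the data were seen.

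Knockout was compared with wild type in limma 3.58.1 (R 4.3.3) with a two-group model, a moderated test with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. Probe sets in the lowest 40% by mean signal over all 6 arrays were left out, which left 14046. Tnfsf10 was tested without this filter, which it does not pass. Differences are knockout minus wild type on the log2 scale. Gene lists, 31 with 688 of 751 symbols found on the array, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, on 1 probe set per gene, that of the highest mean signal. An estimated correlation and fry were run beside it. Another 4 lists (stratified squamous epithelium, stomach epithelium, exocrine pancreas and lung epithelium) were written after the genes leading single arrays had been seen, and serve only to describe arrays. Genes within 10 Mb of Tnfsf10 were compared with all others by a two-sided Fisher's exact test, with neighbours taken from the assembly GRCm38.p6. The array's own build is not given in the sources used here, so no coordinates are printed.

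Named genes followed a rule fixed before the data were examined. It took all Tnfsf10 probe sets, 12 genes higher and 12 lower in the knockout whose groups did not overlap, and up to 4 members of each list with the lowest p. Since none passed the threshold, the 12 places in each direction were filled by the lowest unadjusted p. Genes named to describe single arrays were chosen after their values were seen, as were other genes named near Tnfsf10.

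The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a 60% filter, other forms of the moderated test, array weights, a Student t-test, a replicate block, windows of 5 and 20 Mb, and leaving out each array. Runs without several arrays were added after the data were seen. The fits were tested on simulated data with the real means and spreads, 14046 probe sets and 200 changed. Noise was drawn independently for each probe set, while on the real arrays wild type 1 differs on many probe sets at once. Of the unchanged simulated probe sets, 5.52% had an unadjusted limma p under 0.05, against 89 of 14046 in the real data. The shares below therefore test the code and do not give the power of this comparison. With the spread of the 6 arrays, 45% of 2-fold and 68% of 4-fold changes were recovered and 3 unchanged probe sets were called. With the spread of 5 arrays, without wild type 1, the shares were 62% and 92% and 4 were called.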

Results

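Gene expression was measured on 6 one-colour arrays, with samples labelled as mouse aorta. Per the labels, 3 arrays held RNA from Trail knockout mice and 3 held RNA from wild-type C57Bl6/J mice, all 6 weeks old. Trail is the product of Tnfsf10, a death ligand of the tumour necrosis factor superfamily. The comparison asked which transcripts differ in the aorta when this gene is missing. Median signals over the annotated probe sets lay between 6.34 and 6.47 on the log2 scale on the 6 arrays. The small number of arrays limits the precision of every value, and since the labels do not say how the samples of a group relate beyond being separate, p-values measure the spread between these samples only.

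The deleted gene was examined on every array. Tnfsf10, measured by 1 probe set, had a log2 signal of 8.42 on the array labelled wild type 1. The arrays labelled wild type 2 and wild type 3 gave 4.90 and 4.85, and the arrays labelled knockout 1, 2 and 3 gave 5.02, 4.48 and 4.09. The mean was 4.53 ± 0.47 (SD, n = 3) in the knockout group and 6.06 ± 2.05 (SD, n = 3) in the wild-type group. The difference, knockout minus wild type, was -1.53 (SE 0.98, 95% interval -3.91 to 0.85, limma adjusted p = 0.951). Leaving out the array labelled wild type 1 gave -0.35 (SE 0.25, 95% interval -0.94 to 0.25, limma adjusted p = 0.999). Tnfsf10 therefore did not set the arrays labelled wild type 2 and 3 apart from the knockout arrays, and whether its probe set lies in the deleted part of the gene is not known. Directions below follow the labels.

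**Figure D1:**
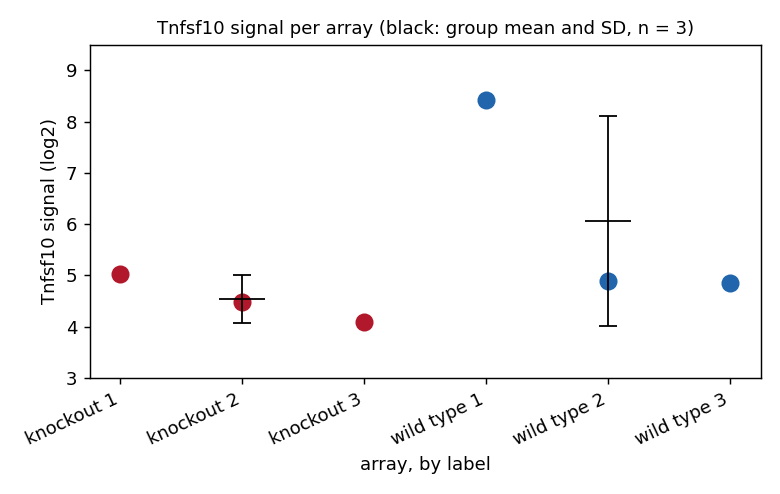
Tnfsf10 signal on the log2 scale (vertical axis) on each array, by its label (horizontal axis), with knockout arrays in red, wild-type arrays in blue, and the mean and SD of each group of 3 in black. The array labelled wild type 1 sits at 8.42 and the other 5 arrays sit between 4.09 and 5.02.

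The array labelled wild type 1 carried a different set of tissue genes from the other 5. All 21 skeletal muscle markers were over 2-fold below every other array there, with a list median of 5.87 against 11.40 to 11.92. Acta1, skeletal muscle actin, gave 7.28 there and 12.998 or more elsewhere. Among genes of stratified squamous epithelium, a list written after the leading genes of the arrays had been seen, 30 of 30 were over 2-fold below all other arrays, and Krt4, a keratin of that epithelium, gave 5.09 there and at least 12.90 elsewhere. In the other direction, 14 of 17 brown fat markers and 19 of 22 white fat and lipid storage genes were over 2-fold above all other arrays on the array labelled wild type 1. Ucp1, the uncoupling protein of brown fat, reached 12.32 there and at most 4.59 elsewhere. The interferon-inducible GTPase Iigp1 reached 11.60 there and at most 6.46 elsewhere, and 17 of 26 interferon-stimulated genes, 18 of 20 fatty acid oxidation genes and 10 of 26 endothelial markers were over 2-fold above all other arrays. In all, 1076 of 23410 annotated probe sets were over 2-fold above, and 1059 over 2-fold below, every other array on this array. Across probe sets, which are not independent replicates, its Pearson r with the others was 0.899 to 0.907, and r among the other 5 was 0.974 to 0.996.

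Genes of further organs stood out on single knockout arrays. On the array labelled knockout 2, 270 probe sets were over 2-fold above all others. The stomach epithelium list, also written after the leading genes had been seen, had a median of 11.46 there, 6.46 on the array labelled wild type 3 and 4.78 to 5.23 on the remaining arrays. Clps and Pla2g1b, which encode pancreatic colipase and phospholipase, gave 13.10 and 13.29 on the array labelled knockout 2, and 5 of 21 exocrine pancreas genes were over 2-fold above the 4 arrays other than it and wild type 1. On the array labelled knockout 1, the surfactant gene Sftpc gave 11.88 against at most 4.87 elsewhere, and the lung epithelium list had a median of 7.42 against 5.20 to 5.61. Vascular smooth muscle genes had list medians of 9.40 to 10.23 on the 6 arrays, and Acta2, smooth muscle actin, lay between 12.27 and 12.63. On the array labelled wild type 1, 6 of 24 of these genes were over 2-fold below all others, among them Actg2 with 8.03 against at least 10.67. Xist lay between 9.62 and 10.37 on all arrays, and the Y-linked genes Eif2s3y, Kdm5d and Uty did not exceed 4.29, so the arrays did not differ in these sex-linked genes.

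**Figure D2:**
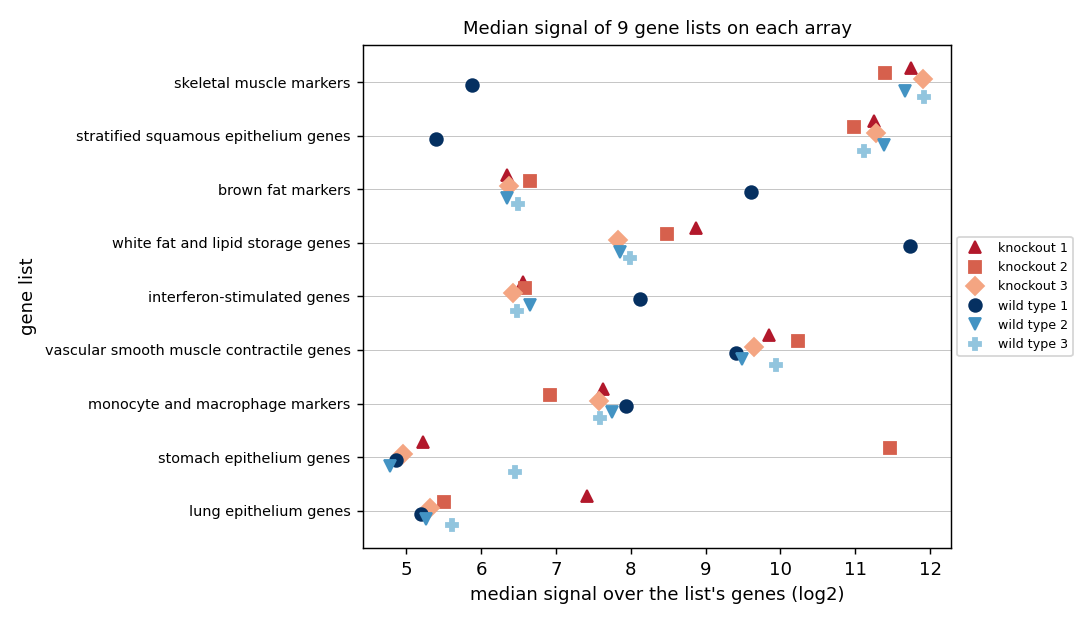
Median log2 signal (horizontal axis) over the genes of each of 9 lists (vertical axis), with a symbol for each array. Skeletal muscle markers have a median of 5.87 on the array labelled wild type 1 and at least 11.40 on the others, while stomach epithelium genes have a median of 11.46 on the array labelled knockout 2.

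No single gene passed the test between the genotypes. Among genes higher on all 3 knockout arrays than on all 3 wild-type arrays, Slc2a1, the glucose transporter GLUT1, differed by 0.83 (SE 0.26, 1.77-fold; 0.55 without wild type 1) and Ddit4, a stress-induced inhibitor of mTOR signalling, by 0.44 (SE 0.12). Among genes lower on all 3, the clock gene Per1 differed by -0.64 (SE 0.12, 1.56-fold), the centrin gene Cetn4 by -0.78 (SE 0.15), and Adamts1, a secreted metalloproteinase, by -0.55 (SE 0.14). Each had a limma adjusted p of 0.921. In limma, 0 of 14046 probe sets passed at an adjusted p under 0.05, and 89 had an unadjusted p under 0.05 (14 higher and 75 lower in the knockout), where chance alone would give about 702. An unmoderated test, run as an alternative, also passed 0 and had 184 under 0.05. The groups did not overlap for 787 probe sets (5.6%), and chance gives 10%. On the 5 arrays other than wild type 1, 0 passed and 217 had an unadjusted p under 0.05 (45 higher, 172 lower).

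The fixed rule picked further genes in each direction, none past the threshold. Higher in the knockout were Sprr2d, a cornified envelope gene, by 1.41 (SE 0.47), Cpm by 0.92 (SE 0.37; 0.54 without knockout 2, where it was highest at 7.44), the vasopressin receptor gene Avpr1a by 0.73 (SE 0.28), and Rab4a, Bend5, Zfp503, Ptpru, Tfap4, Pde9a and Ifna5 by 0.24 to 0.39. Lower were Odf3l1 by -0.56 (SE 0.17), Tppp by -0.54 (SE 0.16), the cold-inducible RNA-binding protein gene Rbm3 by -0.43 (SE 0.13), and Spsb1, Zfp715, Nfya, Cwf19l1, Naa16 and Cdr2 by -0.32 to -0.50. The limma adjusted p was 0.921 for each. Without wild type 1, where they were lowest at 4.67 and 6.11, Sprr2d was at 1.09 and Avpr1a at 0.49. Sprr2d was highest at 7.58 on knockout 2, the array with stomach genes. Cetn4 had 1 further probe set and Rbm3 had 2, all of the same sign as the value given.

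Gene lists were then compared between the genotypes, and 11 of 31 lists shifted with the preset correlation of 0.01 (3 higher, 8 lower in the knockout). None shifted with a correlation estimated from the data, where the lowest adjusted p was 0.677, and none had an FDR under 0.05 in fry. Skeletal muscle markers were higher for 21 of 21 genes, with a median difference of 1.46 (camera adjusted p = 1.07e-06, and adjusted p = 0.837 with an estimated correlation). Examples were Acta1 by 1.89 (SE 1.63) and the troponin gene Tnnt3 by 1.91 (SE 1.67), whose low value came from the array labelled wild type 1 and which without it differed by -0.08 and -0.10. Without that array the list was lower for 21 of 21 genes, with a median of -0.156 (adjusted p = 0.00424, and adjusted p = 0.768 with an estimated correlation), and leaving out knockout 2 as well gave -0.0249 (adjusted p = 0.737) and wild type 3 as well -0.043 (adjusted p = 0.831), against -0.337 without knockout 3 and -0.305 without wild type 2. With wild type 1 kept, the median of 1.46 became 2.27 without wild type 2 and 2.38 without wild type 3. Wild type 1 has more weight in its group there, so the larger medians do not strengthen the shift.

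Lists of fat, mitochondrial and interferon genes shifted lower in the knockout. Brown fat markers were lower for 13 of 14 genes (median -0.713, adjusted p = 0.00686), with Cox8b at -1.18 (SE 0.60). White fat and lipid storage genes were lower for 20 of 21 (median -0.610, adjusted p = 0.0438), with the glucose transporter gene Slc2a4 at -0.39 (SE 0.25). Fatty acid oxidation genes were lower for 19 of 20 (median -0.723, adjusted p = 0.000645), with the uncoupling protein gene Ucp3 at -1.64 (SE 0.62). Oxidative phosphorylation genes were lower for 28 of 28 (median -0.395, adjusted p = 8.2e-05), with Ndufs1 of complex I at -0.50 (SE 0.36). Interferon-stimulated genes were lower for 21 of 22 (median -0.651, adjusted p = 0.00107), with Usp18 at -0.72 (SE 0.38). Each of these 5 lists had an adjusted p = 0.837 with an estimated correlation. Without the array labelled wild type 1, which held the high values of all 5, the median was 0.0429 for brown fat (adjusted p = 0.329), 0.343 for white fat (adjusted p = 6.87e-09, higher for 18 of 21 genes, and adjusted p = 0.765 with an estimated correlation), -0.00301 for fatty acid oxidation (adjusted p = 0.905), -0.00928 for oxidative phosphorylation (adjusted p = 0.346) and 0.0234 for interferon-stimulated genes (adjusted p = 0.25). On leaving out another array of the 6, white fat lost its call without knockout 3 (median -0.439, adjusted p = 0.48), and without wild type 2 or 3 the medians of the 5 lists were larger in size, up to -1.15 for white fat, -1.13 for fatty acid oxidation, -1.08 for interferon-stimulated genes, -1.07 for brown fat and -0.633 for oxidative phosphorylation. Leaving out wild type 2 or 3 gives wild type 1 more weight in its group, so the larger medians do not strengthen these shifts. Without wild type 1, white fat genes were above the mean of the other 4 arrays on knockout 1 and 2 (by 0.444 and 0.458), the arrays with lung and with stomach genes. White fat genes were below the mean of the other 4 on knockout 3 (-0.369), and knockout 3 alone against wild type 2 and 3 gave -0.0338. Their 5-array median was 0.180 without knockout 1 and 0.223 without wild type 2, with calls in both. Of the genes named, Ucp3 was at -0.94 without wild type 1, Cox8b at -0.54, Usp18 at -0.29, Slc2a4 at -0.13 and Ndufs1 at -0.10.

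Macrophage, clock, immediate early and smooth muscle genes shifted in the same direction with and without the array labelled wild type 1, but each lost its call on the 5 arrays when 1 further array was left out. With an estimated correlation the adjusted p was 0.677 for the clock list and 0.837 for the other 3 on 6 arrays, and at least 0.765 for each on 5 arrays. Monocyte and macrophage markers were lower in the knockout for 25 of 27 genes (median -0.370, adjusted p = 8.44e-06), with the macrophage surface gene Adgre1 at -0.49 (SE 0.17), Cd14 at -0.40 (SE 0.17) and the complement gene C1qb at -0.37 (SE 0.18). Without that array 23 of 27 were lower (median -0.198, adjusted p = 0.00975), and the array labelled knockout 2, with the stomach genes, had the lowest list median, 6.92 against 7.57 to 7.93. The macrophage median was -0.174 without knockout 2 (adjusted p = 0.0386), -0.0231 without wild type 1 and knockout 2 (adjusted p = 0.918), -0.141 without wild type 1 and 2 (adjusted p = 0.104), and -0.0808 for knockout 3 against wild type 2 and 3 (adjusted p = 0.156). C1qb was at -0.24 without wild type 1. Circadian clock genes were lower for 12 of 16 (median -0.305, adjusted p = 0.00107), with Per1 at -0.64, Hlf at -0.41 (SE 0.15), Per2 at -0.39 (SE 0.15) and Per3 at -0.48 (SE 0.19). Per1 was the 1 clock gene that passed when adjusted over the list alone, against 0 over all genes tested. Without the array labelled wild type 1 the clock median was -0.264 (adjusted p = 7.55e-05), Hlf was at -0.27 and Per3 at -0.28. The clock list had an adjusted p of 0.0617 without wild type 3, and of 0.0758 without wild type 1 and 3 (median -0.161). Immediate early genes, which respond fast to handling and stress, were lower for 18 of 24 (median -0.311, adjusted p = 0.0148), with Nr4a1 at -1.17 (SE 0.47) and Dusp1 at -0.81 (SE 0.31). Without the array labelled wild type 1 their median was -0.152 (adjusted p = 0.00521), with Nr4a1 at -0.66 and Dusp1 at -0.48, and leaving out wild type 2 as well gave -0.0645 (adjusted p = 0.0512), or knockout 2 as well -0.0701 (adjusted p = 0.000686). Vascular smooth muscle contractile genes were higher for 17 of 24 (median 0.145, adjusted p = 0.00686), with Synpo2 at 0.40 (SE 0.24), and without wild type 1 for 20 of 24 (median 0.0504, adjusted p = 0.042). Their median was 0.0151 without knockout 2 (adjusted p = 0.4), 0.0794 without wild type 2 (adjusted p = 0.422), 0.311 without knockout 3 and 0.273 without wild type 3, and without wild type 1 and 2 their median turned to -0.137 (adjusted p = 0.0198). Ribosomal protein genes were higher for 16 of 17 (median 0.117, adjusted p = 0.0023, and adjusted p = 0.837 with an estimated correlation), and their median was -0.0546 without the array labelled wild type 1 (adjusted p = 0.583), 0.0864 without knockout 3 (adjusted p = 0.0768) and 0.208 without wild type 2.

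**Figure D3:**
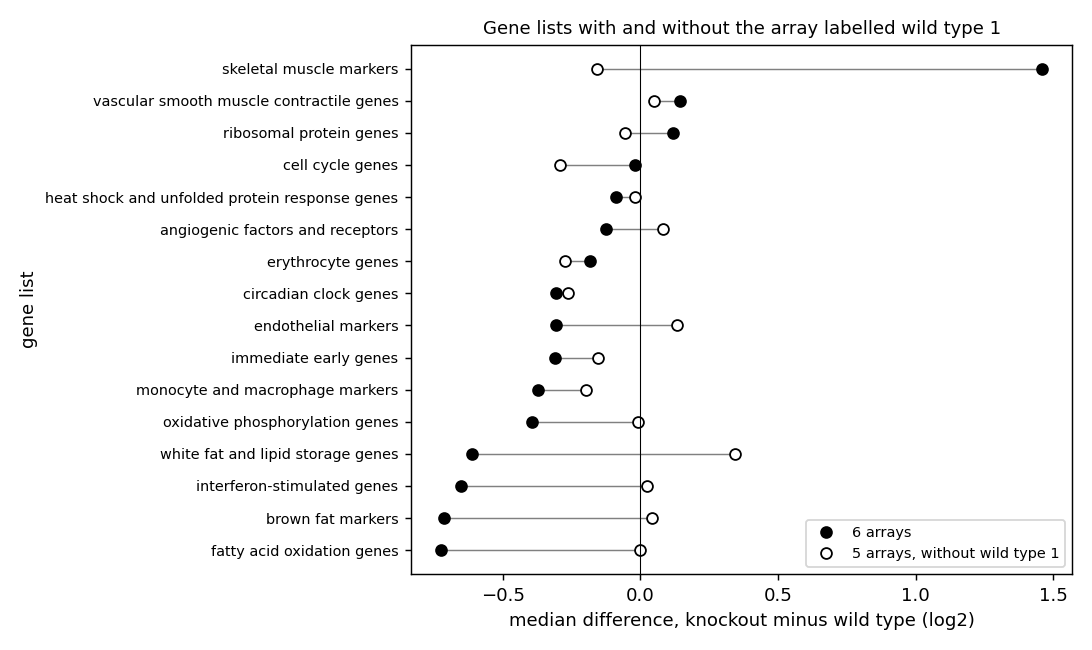
Median log2 difference, knockout minus wild type (horizontal axis), of the 16 lists that shifted with 6 arrays or with 5 (vertical axis). Filled points use all 6 arrays and open points leave out the array labelled wild type 1, where skeletal muscle markers move from 1.46 to -0.156 and circadian clock genes from -0.305 to -0.264.

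The remaining 20 lists did not pass on 6 arrays. TNF superfamily ligands and receptors had 7 of 17 genes higher in the knockout (camera adjusted p = 0.661), and Tnfrsf10b, the mouse Trail receptor, differed by -0.24 (SE 0.21) on 6 arrays and by -0.02 (SE 0.12) without wild type 1. Apoptosis machinery had 16 of 24 genes lower (adjusted p = 0.446), with Diablo, an inhibitor of caspase-blocking proteins, at -0.39 (SE 0.15). Inflammatory cytokines and chemokines had 11 of 18 lower (adjusted p = 0.881), with Csf1 at -0.32 (SE 0.13) and Ccl2 at 0.21 (SE 0.15). The adjusted p was 0.831 for NF-kB targets, 0.6 for T, NK and B cell markers, 0.178 for granulocyte and mast cell markers, 0.446 for fibroblast and matrix genes, 0.498 for matrix metalloproteinases and inhibitors, 0.661 for osteogenic genes, 0.498 for NADPH oxidase and antioxidant genes and 0.971 for cholesterol genes. It was 0.553 for cardiac muscle markers, 0.831 for nerve and Schwann cell markers, 0.881 for glycolysis genes and 0.881 for sex-linked genes. Endothelial markers (adjusted p = 0.0599), angiogenic factors (0.272), erythrocyte genes (0.104), cell cycle genes (0.812) and heat shock and unfolded protein response genes (0.272) did not pass on 6 arrays and passed without the array labelled wild type 1, but not with an estimated correlation there (adjusted p = 0.765 for each). The median, mean and test differed in sign for TNF superfamily, NF-kB, fibroblast and matrix, osteogenic and sex-linked genes.

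Genes near Tnfsf10 on its chromosome were compared with all other genes, because a knockout made in stem cells of another strain can keep donor sequence beside the target. Within 10 Mb, 2 of 52 tested genes (3.85%), Exosc9 and Cetn4, had an unadjusted p under 0.05, against 69 of 11967 elsewhere (0.577%). Both were lower in the knockout, Exosc9 by -0.50 (SE 0.17). The odds ratio was 6.89 (95% interval 0.797 to 27.2, two-sided Fisher's exact test p = 0.0377), and within 5 Mb 0 of 18 genes qualified. On the 5 arrays other than wild type 1, 6 of 52 qualified, all lower in the knockout, with an odds ratio of 9.21 (95% interval 3.17 to 22.0, Fisher's exact test p = 9.59e-05). Neighbouring genes are not independent, so these p-values are too small to the extent that neighbours vary together.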

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

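Runs on all probe sets, on 5 arrays with robust moderation or an estimated correlation, on knockout 3 against wild type 2 and 3, near Tnfsf10 without wild type 1, and on the 5 arrays less each further array were chosen after seeing the data. The 24 named genes kept direction and side of the threshold in all 432 runs. Their direction was largely fixed by the choice, since groups that do not overlap keep their sign when any array is left out. It is therefore no measure of robustness. Where both groups had more than 1 sample, the lowest limma adjusted p of the named genes was 0.767 to 0.998 per setting. Tnfsf10 kept its sign in 12 of 12 runs, from -0.35 without wild type 1 to -2.13 without wild type 3. In every run that kept wild type 1, its signal of 8.42 against at most 5.02 elsewhere fixed the sign. Without wild type 1 the 95% interval, -0.94 to 0.25, included 0. The count of runs is therefore no measure of robustness either. The count of 0 passing probe sets changed to 17 when an unadjusted p under 0.05 with a fold of at least 1.5 was asked, and to 4 (Alox15, Saa3, Snord14e and Prg4, named after their values were seen, all lower) for knockout 3 against wild type 2 and 3, where the lone sample is assumed to vary like the others. The 89 probe sets at an unadjusted p under 0.05 became 295 with no filter and 53 with 60% left out (more and fewer tested), 611 with array weights, 184 with the Student t-test, 197 over all probe sets, 214 with robust moderation on 5 arrays, 218 for knockout 3 against wild type 2 and 3, and 27 (without knockout 2) to 236 (without knockout 3) on leaving out an array, with 41 without knockout 1, 217 without wild type 1 and 159 without wild type 3; the cause was not tested. The 11 shifted lists became 0 with an estimated correlation, on 6 arrays and on 5, and 8 for knockout 3 against wild type 2 and 3. Of the 11, 4 kept call and direction without wild type 1. Medians reversed without wild type 1, with either correlation: on leaving out each array, interferon genes ranged from -1.08 to 0.0234, brown fat from -1.07 to 0.0429, white fat from -1.15 to 0.343, skeletal muscle from -0.156 to 2.38 and ribosomal genes from -0.0546 to 0.208. For knockout 3 against wild type 2 and 3, smooth muscle reversed to -0.188, brown fat to 0.0972, oxidative phosphorylation to 0.0436 and fatty acid oxidation to 0.0277; the cause was not tested. Of the lists called without wild type 1, leaving out each of the 5 arrays moved smooth muscle from -0.137 to 0.222, endothelial markers from -0.0147 to 0.230 and angiogenic factors from -0.0199 to 0.128; over all 11 such lists, 39 of 55 runs kept call and direction, 12 lost the call and 4 reversed. At the preset correlation with all 6 arrays, 2 calls were lost to processing, while their medians did not shrink. They were white fat with median centring (median -0.645, camera adjusted p = 0.128) and smooth muscle with no filter (median 0.145, camera adjusted p = 0.0502). Leaving out 1 array other than wild type 1 ended the calls of white fat (without knockout 3, adjusted p = 0.48) and ribosomal genes (without knockout 3, 0.0768). It also ended those of smooth muscle (without knockout 2, 0.4, or wild type 2, 0.422) and the clock list (without wild type 3, 0.0617). The odds ratio near Tnfsf10 was 0 within 5 Mb, where 18 genes were tested, 6.38 within 20 Mb and 39.0 at an unadjusted p under 0.01. With the replicate block, 0 probe sets passed, 73 had an unadjusted p under 0.05 and 12 lists shifted; deviations of equal replicate numbers correlated at 0.0946, -0.231 and 0.198, so the numbers were not taken to pair the samples. Dim probe sets, Tnfsf10 on 5 arrays among them, are limited by background.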

Other observations

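The comparison of all 6 arrays, with its counts and the odds ratio near Tnfsf10, and the counts and lists at the preset correlation without wild type 1 were planned before the data were examined; of the tests of explanations, that of quantile normalization was set before its result was seen, while the others, the estimated correlation and the genes near Tnfsf10 without wild type 1, and leaving out an array besides it were chosen, or had their bounds corrected, after results were seen. Without the array labelled wild type 1, 5 lists that did not pass on 6 arrays shifted at the preset correlation, and none with an estimated one (adjusted p = 0.765 for each). Cell cycle genes were lower in the knockout for 23 of 24 genes (median -0.291, camera adjusted p = 2.52e-09), with the replication gene Mcm5 at -0.37 (SE 0.15) and Pcna, the sliding clamp of replication, at -0.34 (SE 0.16). The array labelled wild type 2 was highest for 20 of 27 of these genes, and leaving it out as well gave a median of -0.0883, against -0.496 without wild type 3. That array was also highest for 21 of 30 stratified squamous epithelium genes, and a link between these patterns was not tested. Endothelial markers were higher for 21 of 25 (median 0.132, adjusted p = 0.000365), with Plvap at 0.49 (SE 0.26), and angiogenic factors for 15 of 27 (median 0.0822, adjusted p = 0.0109). Both rested on knockout 1, the array with lung genes, as leaving it out too gave medians of -0.0147 (adjusted p = 0.623) and -0.0199 (adjusted p = 0.583), and the angiogenic call also ended without wild type 2 (adjusted p = 0.104); the endothelial median was 0.230 without knockout 2 and the angiogenic 0.128 without knockout 3. Heat shock genes were lower for 14 of 25 and higher for 11 (median -0.0196, camera adjusted p = 0.042), so the list had no common direction. Its chaperone genes Hspa1a and Dnajb1 were at -0.95 (SE 0.16) and -0.70 (SE 0.17), against -0.58 and -0.38 on 6 arrays. For erythrocyte genes, 3 of 3 were lower (median -0.275, camera adjusted p = 0.00975). Leaving out knockout 1 as well ended the heat shock call (median -0.0123, adjusted p = 0.405) and the erythrocyte call (median -0.213, adjusted p = 0.126). The heat shock call also ended without knockout 3 (median -0.0353, adjusted p = 0.43) or wild type 3 (median -0.0882, adjusted p = 0.125), where the median grew in size, as it did without knockout 2 with the call kept (median -0.0795, adjusted p = 6.55e-05). No gene passed over all genes (lowest limma adjusted p = 0.997, with 217 at an unadjusted p under 0.05).

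The array labelled wild type 1 stood apart from the other 5. A failed hybridization would narrow its signals, but their SD was 2.118, within the 2.041 to 2.150 of the others. How the deposited values were scaled is not known, and scaling to a common spread would hide a narrowing. The SD therefore does not decide. After quantile normalization the highest r of this array was still 0.908 against at least 0.974 among the others. If the labels hold, Trail genotype would place wild type 2 and 3 beside it, yet without it the skeletal muscle list differed between the groups by a median of -0.156; if wild type 2 and 3 are knockout samples, genotype and this array are confounded, and the list's median of -4.95 against the mean of the other 5 arrays cannot be told apart from a genotype effect. A different tissue make-up of the samples is a candidate explanation, as 21 of 21 skeletal muscle markers were over 2-fold lower on it. The high skeletal muscle signals lay on the other 5 arrays (list medians 11.40 to 11.92). Those 5 also held high squamous epithelium signals, with list medians of 10.98 to 11.39 against 5.40 on the array labelled wild type 1. The labels give aorta for all 6 samples. The 21 skeletal muscle markers were fixed beforehand and high on all 5 arrays, which argues against aorta alone on those arrays. Which tissues the 5 arrays hold was not tested, and whether wild type 1 holds aorta alone is not known. Comparisons on the 5 arrays are between samples that share these muscle and epithelium signals. For RNA of neighbouring organs on single arrays, the bound was a majority of the 16 lung genes not seen when the list was written. It was missed, with 7 over 2-fold above the other 4 arrays on knockout 1. No other array of the 5 had any (0), and 4 of the 16 lay under the low-signal limit on all 5. On knockout 2, 19 of 20 stomach epithelium genes were over 2-fold above the other 4 arrays, by a median of 6.19 over their mean. That list was written after its leading genes were seen, so it describes the array and tests nothing. The explanation stays open, and the missed bound does not argue against it.

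Tnfsf10 was high only on the array labelled wild type 1. As its cause, a swap between the groups would need a knockout array with a high signal, and the highest was 5.02; a swap of arrays with little Tnfsf10 RNA would leave no such trace and is not excluded. Wild type 2 and 3 could be knockout samples under a wrong label, or may hold little Tnfsf10 RNA, and these cannot be told apart. The array labelled wild type 1 also differed in tissue genes, and 17 of 26 interferon-stimulated genes were over 2-fold above all others there. Its high Tnfsf10 signal therefore cannot be tied to genotype, nor taken as the usual wild-type level. The window around Tnfsf10 ranked above all 11897 other windows (percentile 100) without wild type 1, which by the bound set would speak against a wrong label. However, 3 of the 9 other splits of the 5 arrays also passed the 95th percentile, so that bound did not separate genotype from other structure. No other split reached the labelled one. The highest other percentile was 99.71, and the highest other odds ratio was 6.43 against 9.21. With 10 splits, the largest value alone cannot give a share under 0.05. The windows were centred on tested genes and overlap, so a rank among 11897 windows is not a rank among separate regions. The difference in Tnfsf10 without wild type 1, -0.35, had an interval that includes 0.

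Genes near Tnfsf10 were more often at an unadjusted p under 0.05, and donor-strain sequence kept beside the deleted gene is a possible explanation. The window ranked at the 99.5 percentile on 6 arrays, among windows that overlap. However, 3 of the 9 other splits passed the 95th percentile too, the highest at 99.66, so the rank does not decide. Donor-strain bases under the probes would lower signals, and 0 of the 6 genes qualifying without wild type 1 were higher in the knockout. However, 75.4% of other genes at that p were lower as well, which gives 0.184 by chance if the 6 genes are independent. Neighbours that vary together would make this value larger. Of the 10 splits of the 6 arrays, only the real one had an odds ratio as large as 6.89, and the highest other was 6.61. Splits of 3 against 3 are too few for a share under 0.05.

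For the counts, the labelled grouping did not stand out among the splits. The real split gave 89 probe sets at an unadjusted p under 0.05, and 7 of the 10 splits, counting the real one, gave as many. The highest other, 1199, joined knockout 1 and 2 with wild type 1, which points to a structure of the samples, of untested cause. The real split gave 11 shifted lists, 5 of the 10, counting the real one, gave as many, and the highest other gave 14.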
